A study of Mus musculus with 10 samples.

How the data were processed

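Single-cell RNA was measured in 10 droplet libraries from left kidneys of female mice, 2 mice in each of 5 groups: aged controls, aged mutants, sham mutants, injured controls and injured mutants. Per the labels' protocols, mice were perfused with PBS, red cells were lysed, live CD45+, Lotus lectin-positive and double-negative cells were sorted, and similar numbers from each gate were pooled and loaded for 10x Chromium 3′ version 3 libraries. The labels describe more than one digestion and do not say which was used for these libraries. The deposited files hold UMI counts per gene and barcode, and all values were whole numbers. Per the submitters' processing notes, Cell Ranger 5.0.1, Seurat 3.1.5 and the mm10 genome were used; the role of each tool in these files is not given in the sources used here. Every barcode had at least 500 UMIs, so barcodes had been filtered before deposit. The 79355 barcodes match the number of cells that the series' design text states. Total counts per library ran from 19009502 to 55639021 UMIs. Of 31053 gene identifiers 30934 were matched to GENCODE vM21, from which positions on mm10 were taken, and 56 share a symbol with another.

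Cells with at least 200 genes and at most 50% mitochondrial UMIs were kept, 61309 in all. Likely doublets were scored per library against simulated pairs. Of the kept cells 0.8% were marked per 1000 barcodes in the library before this filter, which gave 4188 that were then left out. Counts were scaled to 10000 UMIs per cell and logged, and 2000 variable genes, 40 principal components, 20 neighbours and Leiden clustering at resolution 1 were used over all libraries together (scanpy 1.11.5, leidenalg 0.10.2, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). Clusters were named by the mean z score of marker lists, with a score of at least 0.5 and at least 3 markers detected in 10% of cells, and immune cells were clustered again and named in the same way. A cluster stayed unnamed where its best score was too low, over 50% of its cells were marked as doublets, or markers of another type led. The same held where at most 0.5 of its type's markers were detected and a second type scored at least 1. It also held where depth was low without its own markers leading. Immune clusters left unnamed kept the name their cells had among all cells, unless they were likely doublets or shallow without own markers. Each class name stands for cells like that type by these markers, not for a type shown by other means. For tests of genes the T cell subsets were pooled into T cells, and conventional (1 and 2) and migratory dendritic cells into dendritic cells, so a change in these classes can come from a change in their make-up.

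UMIs were summed per library and class. Libraries with at least 10 cells of a class entered its fit, and a class was tested where both libraries of each group compared had at least 20 cells. Sums were made for 18 classes, of which 11 to 15 were tested in a contrast. Genes were tested with edgeR 4.0.16 (quasi-likelihood, TMM scaling, low-count filter, 1 coefficient per group over all 10 libraries) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05 within class and contrast. Standard errors were derived from the fold change and the F statistic. Gene lists, 25 in all and with at least 5 measured members, were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and adjusted over lists and classes. Counts of immune types with at least 50 cells were tested with edgeR against the library's immune cells, and CD45-negative types against its CD45-negative cells outside the proximal tubule. All tests were two-sided. The p-values of tests of genes and cell types measure the spread between mice, and intervals and floors cover counting error only. At the preset correlation the camera p-values set a list's members against other genes and do not measure that spread. A gene with 0 UMIs in a group was compared with a floor of 3 counts over that group, and a gene with 1 to 3 UMIs is given as a ratio with its exact 95% counting interval. The 6 contrasts were aged mutants against aged controls, injured mutants against injured controls, injured against sham mutants, injured against aged mutants, injured against aged controls, and the difference between the genotype effects of the injury and the aged cohort. The groups, contrasts, lists and most alternatives were fixed before the data were examined.

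Genes named in the text were chosen by rule: in each contrast within a cohort, up to 5 risen and 5 fallen with the largest change in each of the 3 classes with most calls, with libraries that did not overlap and a higher group mean of at least 20 CPM, and list members past the test. Mitochondrial, ribosomal, immunoglobulin, T cell receptor, haemoglobin and unnamed predicted genes were not named, nor genes under 0.1 of their mean in the highest class, which free RNA can bring. In the other contrasts 3 risen and 3 fallen came from the class with most calls. Free RNA may also lie above the cut of 0.1. In injured mutants the sum over 13 abundant proximal tubule transcripts was 52976 CPM in proximal tubule cells. It was 6458 CPM in thick ascending limb cells, 8985 CPM in distal convoluted and connecting tubule cells and 3107 CPM in B cells.

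The tests were checked on simulated counts with known answers. For principal cells of aged mutants and aged controls (11041 genes), 34.8% of genes changed 1.5-fold, 68.7% of those changed 2-fold and 92.3% of those changed 4-fold were called, with 0.138% of unchanged genes. For T cells of injured and sham mutants (10428 genes) the shares were 15.2%, 52.4%, 87.7% and 0.0782%. Of cell types changed 3-fold 58.5% were called, and 0.75% of unchanged ones.

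Alternatives were DESeq2 1.42.0 size factors and tests, no low-count filter, a fit with only the compared groups, a mitochondrial limit of 25%, at least 500 genes per cell, doublets kept, clustering at resolutions 2 and 0.5, genes that free RNA can bring left out, 1 adjustment over all classes, an estimated correlation, TMM over types, limma on logit shares, a block for the replicate number, and each library left out, where the lone library of a group is assumed to vary like the other groups. Counts of the aged and injured libraries thinned in each class to the lowest total UMIs among them, with sham libraries as they were, the fit without sham mutant 1 as the smallest library, subsets of principal cell clusters and a crossed block were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.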

Results

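Kidneys of female mice were profiled by droplet-based 3′ single-cell RNA sequencing to look for cells that go with the different pace of cyst growth in injured and uninjured kidneys of cilia mutant mice. The mutants carried an adult-induced, conditional loss of Ift88, which encodes an intraflagellar transport protein needed to build primary cilia. There were 10 libraries in 5 groups of 2 mice. Aged controls and aged mutants were collected about 7 months after induction. Injured controls and injured mutants were collected 8 weeks after 30 min of unilateral ischemia-reperfusion, and sham mutants formed the fifth group. Libraries are called by group and number below, as in aged mutant 2. Live cells were sorted into CD45+ leukocytes, cells binding Lotus lectin (a proximal tubule stain) and cells negative for both, and about 3300 cells from each of the 3 gates were pooled, so the sort and not the kidney sets the balance between these compartments.

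The libraries held 3879 to 10134 barcodes and 19009502 to 55639021 UMIs (unique molecular identifiers, each standing for 1 captured transcript). After filtering, 61309 of 79355 barcodes were kept, between 50.3% of barcodes in sham mutant 1 and 86.5% in aged mutant 1. Median UMIs per kept cell ran from 3303 in injured mutant 2 to 5317.5 in injured control 1. Sham mutant 1 was the smallest library, with 1953 kept cells and 568 immune cells. Replicates of each group differed by more than sampling noise, with a chi-square per degree of freedom of 20.9 for the sham mutants and up to 84.1 for the aged mutants. Cells that could not be named made up 6.90% to 12.2% of the aged libraries other than aged mutant 2, which held 14.2%, and 9.22% to 25.4% of the libraries of the injury cohort.

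Ift88 transcripts (ENSMUSG00000040040; mm10 chromosome 14, 57424062 to 57517936, plus strand, protein coding) differed past the test between mutants and controls in principal cells of the aged cohort alone, of the 6 classes where they were tested. In principal cells, the water- and sodium-reabsorbing cells of the collecting duct, Ift88 averaged 15.7 ± 2.63 CPM (UMI counts scaled to a common library total, mean ± SD, n = 2) in aged controls and 8.90 ± 1.93 CPM in aged mutants, a log2 change of -0.86 ± 0.24 (standard error, edgeR adjusted p = 0.0140). It averaged 18.6 ± 0.572 CPM in injured controls, 10.6 ± 0.613 CPM in injured mutants and 6.04 ± 1.69 CPM in sham mutants. The injured mutant difference of -0.81 did not pass the test (edgeR adjusted p = 0.215). The aged call was lost without aged mutant 2 (adjusted p = 0.191), without aged control 2 (adjusted p = 0.140), with DESeq2 (adjusted p = 0.184), and when counts were thinned to equal totals (adjusted p = 0.158). At clustering resolution 0.5 the direction turned, with a log2 change of 0.27 (adjusted p = 0.494). In proximal tubule cells the log2 differences were -0.71 and -0.82 (aged and injury cohort, edgeR adjusted p = 0.251 and 0.496). Those in thick ascending limb cells were -0.85 and -0.86 (adjusted p = 0.182 and 0.289), and in macrophages -1.16 and -1.71 (adjusted p = 0.144 and 0.884). Endothelial cells had -0.37 and -0.91 (edgeR adjusted p = 0.542 and 0.578). Distal convoluted and connecting tubule cells had -0.51 and -0.56 (edgeR adjusted p = 0.775 and 0.855). At resolution 1 the difference was thus negative in each of the 6 classes in both cohorts. Intercalated cells, where Ift88 was not tested, averaged 16.8 ± 4.13 CPM in aged controls and 16.9 ± 16.3 CPM in aged mutants, from 22 and 8 UMIs. They averaged 8.05 ± 7.14 CPM in injured controls and 2.91 ± 0.0963 CPM in injured mutants, from 9 and 2 UMIs. The 3′ tags may lie outside the deleted exons, in which case these levels check nothing about the mutation.

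The comparison of aged mutants with aged controls asks what the cilia mutation does without injury. Principal cells sat in different clusters in these groups. Cluster 29 held 8 of 771 in aged controls and 576 of 1241 in aged mutants, so changes of genes and lists in this class can come from the mix. In principal cells of aged mutants, Lcn2, an iron-binding acute phase protein used as a marker of tubular damage (chromosome 2, 32384633 to 32388252), rose from 71.3 ± 19.3 to 3384 ± 1623 CPM (log2 change 5.56 ± 0.34, n = 2 per group, edgeR adjusted p = 8.35e-08). Dcdc2a, which encodes a ciliary doublecortin-domain protein (chromosome 13, 25056004 to 25210706), rose from 6.93 ± 3.44 to 376 ± 76.2 CPM (log2 change 5.72 ± 0.24, adjusted p = 4.38e-09). Pigr, the epithelial receptor that carries polymeric immunoglobulin, rose by 5.87 ± 0.46 (adjusted p = 4.53e-07). The kallikrein Klk1, a kinin-releasing protease of the distal nephron (chromosome 7, 44225360 to 44229618), fell from 13681 ± 486 to 347 ± 316 CPM (log2 change -5.32 ± 0.49, adjusted p = 2.12e-06). The urate transporter Slc2a9 (chromosome 5, 38349273 to 38503143) fell from 54.7 ± 1.86 to 1.96 ± 0.451 CPM (-4.85 ± 0.24, adjusted p = 1.1e-08). The vasodilator peptide gene Adm fell by 4.85 on the log2 scale, Hhatl by 4.91 and the defensin Defb2 by 5.02. Il1f6, an epithelial cytokine of the IL-1 family, had 793 UMIs in aged mutants and 0 in aged controls, at least 130-fold higher against a floor of 3 counts over the group. Its edgeR call was not kept by DESeq2 (adjusted p = 0.149). Gxylt2 had a ratio of 57.7 (95% counting interval 15.8 to 479). Klk1 has near-identical paralogs, so its reads are uncertain between family members.

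**Figure D1:**
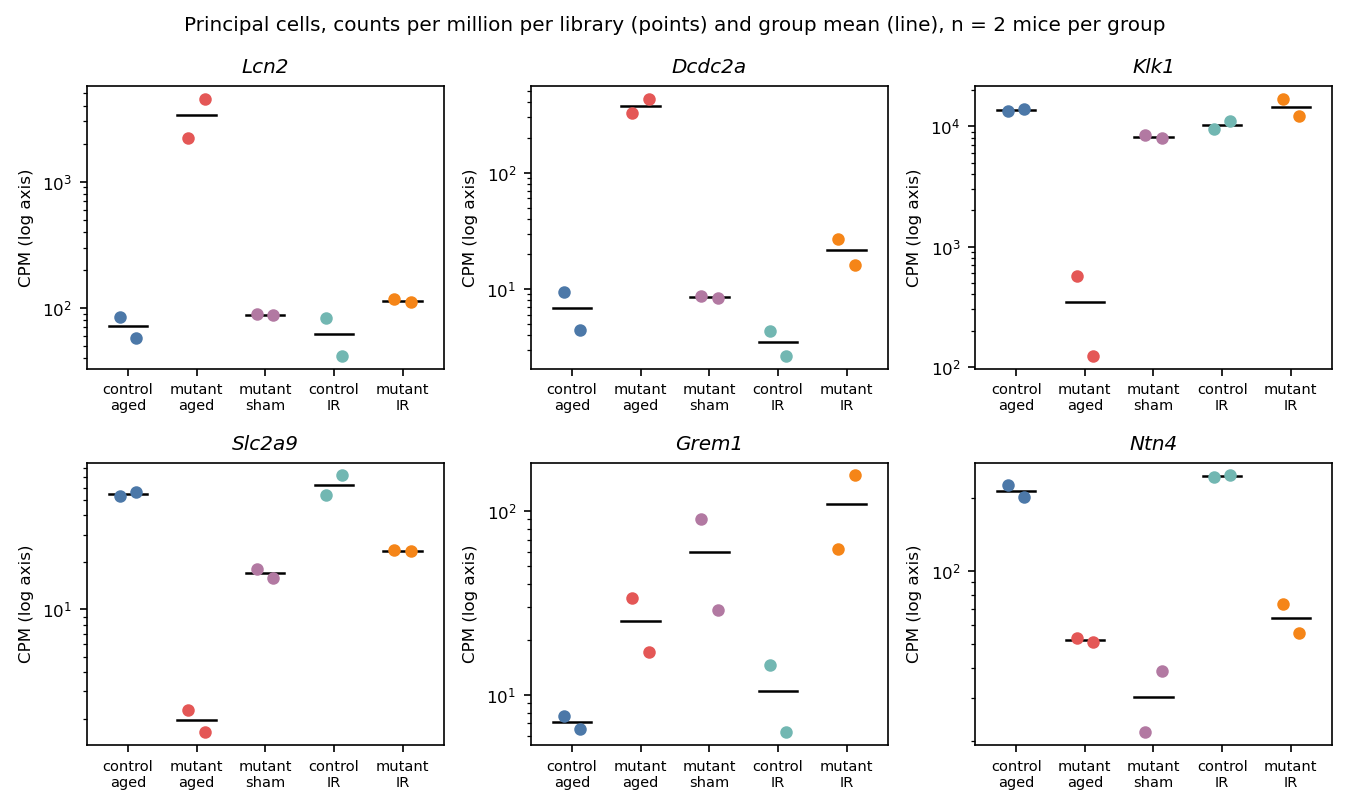
CPM (log axis) of Lcn2, Dcdc2a, Klk1, Slc2a9, Grem1 and Ntn4 in principal cells, with a point per library and a line at the mean of each of the 5 groups. Klk1 averaged 347 CPM in aged mutants and 8227 to 14520 CPM in the other groups, while Ntn4 averaged 30.3 to 64.4 CPM in the mutant groups and 214 to 246 CPM in the controls.

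Cells of the thick ascending limb, the salt-reabsorbing segment of the loop of Henle, shared the rise of Lcn2. Their clusters differed between the groups, with 231 of 438 cells of aged controls in cluster 18 and 312 of 555 of aged mutants in cluster 13, so changes in this class can come from the mix. Lcn2 rose from 4.42 ± 2.60 to 1232 ± 400 CPM (log2 change 8.12 ± 0.50, n = 2 per group, edgeR adjusted p = 1.69e-09). The metalloprotease gene Adamts1 rose by 4.70 ± 0.37 (adjusted p = 4.8e-08). Psca, a surface protein of urothelium, was at least 89.9-fold higher against the floor of 3 counts, a call that DESeq2 did not keep (adjusted p = 0.353). Serpina10 had a ratio of 113 (95% counting interval 20.03 to 4473) and Aoc1, which encodes a diamine oxidase, a ratio of 28.4 (9.55 to 139). Nos1, the neuronal nitric oxide synthase of the macula densa, fell from 76.3 ± 1.64 to 2.59 ± 3.66 CPM (-5.18 ± 0.49, adjusted p = 5.11e-07). Uroc1 fell by 3.49 and Ndst4 by 3.85 on the log2 scale. Pvalb and Calb1, calcium-binding proteins of the neighbouring distal convoluted tubule, fell by 4.89 and 4.14. The Calb1 call was lost without aged control 1 (adjusted p = 0.121) and with DESeq2 (adjusted p = 0.155).

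For lists, counts of classes include members that free RNA can bring unless stated. The tubular injury list, fixed in advance like all 25 lists, was higher in 10 of 13 classes tested. In principal cells 16 of its 19 measured members rose and 1 fell (16 and 1 adjusted over the list alone), with a median log2 change of 1.86 (camera adjusted p = 2.77e-09, and adjusted p = 0.177 with an estimated correlation). Krt19, a keratin of simple epithelia, rose by 4.23 ± 0.30, and Sox9, a transcription factor of repairing tubules, had a ratio of 59.4 (16.3 to 493). In thick ascending limb cells 13 of 18 rose (16 adjusted over the list alone, median 1.59, adjusted p = 1.61e-10, and adjusted p = 0.152 with an estimated correlation). Proximal tubule cells had 13 of 20 higher (16 over the list alone, median 1.44, adjusted p = 2.11e-11, and adjusted p = 0.213 with an estimated correlation). Their cluster 27 held 83 of 2244 cells in aged controls and 554 of 3036 in aged mutants, so the changes of lists in this class can come from that shift. Complement and acute phase genes rose in 5 of 7 classes. All 5 measured members rose in principal cells (5 adjusted over the list alone, median 2.98, adjusted p = 0.000199, and adjusted p = 0.261 with an estimated correlation). Of the same 5, 4 rose in thick ascending limb cells (5 over the list alone, median 4.33, or 3.18 with the member at 0 UMIs at its bound, adjusted p = 3.93e-06, and adjusted p = 0.144 with an estimated correlation). C3, the central complement component, rose by 4.51 ± 0.55 in proximal tubule cells, and C4b by 5.38 ± 0.39 in macrophages.

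Genes of energy metabolism moved the other way in these epithelia. All 17 measured oxidative phosphorylation genes fell in principal cells (17 adjusted over the list alone, median -0.78, camera adjusted p = 3.42e-10, and adjusted p = 0.297 with an estimated correlation). The same 17 fell in thick ascending limb cells (17 over the list alone, median -0.59, adjusted p = 1.28e-09, and adjusted p = 0.335 with an estimated correlation). Sdha, a subunit of succinate dehydrogenase, fell from 290 ± 9.12 to 135 ± 21.2 CPM in principal cells. In macrophages the same list had a median of 0.25, with 2 of 17 members higher (3 over the list alone, adjusted p = 6.39e-05, and adjusted p = 0.334 with an estimated correlation). Over 13 classes it was higher in 4 and lower in 5. Fatty acid oxidation genes were lower in 4 of 12 classes. In principal cells 11 of 16 fell (12 over the list alone, median -0.996, adjusted p = 2.07e-06, and adjusted p = 0.213 with an estimated correlation). Among them were Cpt1a, the carnitine transferase that admits fatty acids to mitochondria (-1.46 ± 0.22), and Ppargc1a, a coactivator of mitochondrial genes (-1.29 ± 0.17). Glycolysis and hypoxia genes were higher in 5 and lower in 1 of 13 classes. In principal cells 2 of 15 rose and 9 fell (3 and 10 over the list alone, median -0.47, adjusted p = 0.0201, and adjusted p = 0.544 with an estimated correlation). Without aged mutant 2 this call was lost (adjusted p = 0.0504). In dendritic cells 4 of 13 rose and 1 fell (7 and 1 over the list alone, median 0.44, adjusted p = 0.00355, and adjusted p = 0.225 with an estimated correlation). The proximal tubule transport and metabolism list was lower in proximal tubule cells, where 1 of 22 members rose and 4 fell (2 and 9 over the list alone, median -0.34, adjusted p = 0.000530, and adjusted p = 0.306 with an estimated correlation). Pck1, the gluconeogenic carboxykinase, fell from 1983 ± 736 to 510 ± 241 CPM. The Pck1 call was lost without aged control 1 (edgeR adjusted p = 0.0889) and without aged mutant 2 (adjusted p = 0.118).

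Signalling and matrix genes rose in principal cells. The extracellular matrix list was higher in 7 of 10 classes, the YAP and TEAD list in 3 of 9 and the TGF-beta and myofibroblast list in 1 of 9, principal cells. In principal cells 7 of 11 extracellular matrix genes rose (9 adjusted over the list alone, median 2.38, camera adjusted p = 0.00110, and adjusted p = 0.306 with an estimated correlation). In the same cells 5 of 11 TGF-beta and myofibroblast genes rose (5 over the list alone, median 1.39, adjusted p = 0.00542, and adjusted p = 0.279 with an estimated correlation). So did 6 of 11 targets of the growth regulators YAP and TEAD (8 over the list alone, median 0.62, adjusted p = 0.000903, and adjusted p = 0.194 with an estimated correlation). The growth factor gene Tgfb2 rose from 2.41 ± 0.515 to 58.1 ± 12.8 CPM and Ankrd1, a YAP target, from 1.42 ± 1.43 to 58.8 ± 17.1 CPM. Cell cycle genes were higher in 6 and lower in 1 of 11 classes. In proximal tubule cells 13 of 20 rose and 1 fell (16 and 1 over the list alone, median 2.84, adjusted p = 3.12e-12, and adjusted p = 0.144 with an estimated correlation). In macrophages 14 of 20 rose (19 over the list alone, median 2.20, adjusted p = 2.58e-10, and adjusted p = 0.279 with an estimated correlation). In T cells no single member passed over all genes, 14 of 20 were lower over the list alone, and the median was -1.03 (adjusted p = 1.06e-05, and adjusted p = 0.335 with an estimated correlation). Immediate early and dissociation stress genes were higher in 4 of 13 classes. Of 22 members 11 were higher and 1 lower in thick ascending limb cells (15 and 1 over the list alone, median 0.90, adjusted p = 2.07e-06, and adjusted p = 0.261 with an estimated correlation). Genes of the inflammatory cytokine and NF-kB list were higher in 2 of 10 classes. Principal cells were among them, with 4 of 7 higher (4 over the list alone, median 1.04, adjusted p = 0.0107, and adjusted p = 0.215 with an estimated correlation). The principal cell call was lost without aged control 1 (adjusted p = 0.115) and without aged mutant 1 (adjusted p = 0.102). The primary cilium and intraflagellar transport list passed the test in 0 of 12 classes, with a smallest camera adjusted p of 0.0543. Within it the polycystin gene Pkd2 rose by 0.66 ± 0.15 in thick ascending limb cells, lost without aged control 2 (edgeR adjusted p = 0.132). Ift20 fell there by 0.64, lost without aged control 1 (adjusted p = 0.109) and aged mutant 2 (adjusted p = 0.103).

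Macrophages of aged mutants carried more transcripts of alternative activation. In macrophages 8 of 12 measured members of the alternative activation and scar-associated list rose (10 adjusted over the list alone, median 1.96, camera adjusted p = 4.87e-08, and adjusted p = 0.194 with an estimated correlation). This list was higher in 8 of 13 classes. In dendritic cells 7 of 10 rose (7 higher and 1 lower over the list alone, median 1.80, adjusted p = 5.425e-05, and adjusted p = 0.161 with an estimated correlation). The dendritic cell call was lost without members that free RNA can bring (median -0.21, adjusted p = 0.440). In macrophages Trem2, a lipid receptor of scar-associated macrophages, rose from 37.2 ± 8.70 to 260 ± 39.8 CPM, and Ccl2, which draws monocytes, from 24.5 ± 19.9 to 186 ± 56.6 CPM. Arginase Arg1 in monocytes was at least 233-fold higher against the floor of 3 counts over the group. The resident macrophage list was higher in 8 of 13 classes. In monocytes 5 of 13 members were higher (9 over the list alone, median 1.42, adjusted p = 3.93e-07, and adjusted p = 0.177 with an estimated correlation). In the clustering of all cells, cluster 26 held 341 of 583 monocytes in aged controls and 165 of 462 in aged mutants. Changes in monocytes, Arg1 among them, can thus come from the mix. The dendritic cell class pools subtypes whose balance shifted, with 159, 203 and 11 cells of types 1, 2 and migratory in aged controls and 83, 375 and 28 in aged mutants, so its changes can come from this shift. In this class Ccl17, a chemokine for T helper and regulatory T cells, rose from 2.31 ± 0.212 to 257 ± 23.7 CPM (log2 change 6.76 ± 0.63, n = 2 per group, edgeR adjusted p = 7.17e-06). The macrophage elastase Mmp12 rose there by 4.10 ± 0.25, the lectin Clec4n by 5.57 ± 0.64 and the fatty acid receptor Ffar2 by 3.69 ± 0.42. Xlr fell by 2.52, Hepacam2 by 2.45 and Cyp8b1 by 2.56. Antigen presentation genes went down in macrophages, where 5 of 11 MHC class I genes fell (6 over the list alone, median -0.38, camera adjusted p = 8.71e-06, and adjusted p = 0.213 with an estimated correlation). There 4 of 8 MHC class II genes fell (6 over the list alone, median -0.42, adjusted p = 0.00184, and adjusted p = 0.362 with an estimated correlation). In proximal tubule cells 4 of 8 MHC class II genes rose (6 over the list alone, median 1.31, adjusted p = 1.95e-05, and adjusted p = 0.306 with an estimated correlation). Of the 403 genes called in proximal tubule cells of aged mutants against aged controls, 158 were ones that free RNA can bring. The MHC class II rise there can thus come from RNA of other cells. Principal cells had 6 of 10 MHC class I genes higher (6 over the list alone, median 0.55, adjusted p = 0.00292, and adjusted p = 0.225 with an estimated correlation). MHC class I was higher in 3 and lower in 4 of 13 classes, and MHC class II higher in 4 and lower in 1 of 10. In the separate clustering of immune cells, different clusters held most macrophages of the aged groups, in controls a cluster numbered 0 and in mutants cluster 8. Cluster 8 was led by Ccl8, Fcrls, Pf4 and Mrc1. It held 0.472% ± 0.203 of immune cells in aged controls and 14.5% ± 3.22 in aged mutants, and cluster 0 held 20.3% ± 1.47 and 5.51% ± 1.93. Changes in macrophages between these groups, Trem2, Ccl2 and C4b among them, can thus come from the mix. In the clustering of all cells a single cluster held most macrophages in both groups, 1427 of 1896 in controls and 1191 of 1352 in mutants.

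Interferon response genes were higher in 2 and lower in 3 of 12 classes. In principal cells 7 of 17 rose and 1 fell (8 and 1 adjusted over the list alone, median 0.89, camera adjusted p = 0.0145, and adjusted p = 0.448 with an estimated correlation). That call was lost without aged mutant 2 (adjusted p = 0.10001) and without members that free RNA can bring (adjusted p = 0.616). In macrophages 0 rose and 1 of 20 fell (3 over the list alone, median -0.42, adjusted p = 0.0333, and adjusted p = 0.679 with an estimated correlation). The macrophage call was lost without aged control 1 (adjusted p = 0.807) without aged mutant 1 (adjusted p = 0.0583) and without such members (adjusted p = 0.121). The T cell class pools subsets whose mix changed, from 359 to 105 cells for T cells without a subset, 187 to 492 for regulatory T cells and 75 to 300 for gamma delta and type 17 T cells, so its changes can come from the mix. Naive lymphocyte genes fell in T cells, where 5 of 10 passed (1 higher and 6 lower over the list alone, median -0.78, adjusted p = 1.93e-05, and adjusted p = 0.306 with an estimated correlation). Satb1, a chromatin organiser of naive T cells, fell from 136 ± 6.24 to 53.1 ± 2.78 CPM and Lef1, a transcription factor of naive T cells, from 138 ± 1.55 to 61.0 ± 1.24 CPM. The type 2 and type 17 cytokine list was higher in T cells, its 1 tested class, with 2 of 6 members higher (4 over the list alone, median 1.32, adjusted p = 0.00542, and adjusted p = 0.213 with an estimated correlation). The T and NK effector list was higher in 1 and lower in 1 of 9 classes. In B cells 2 of 5 members rose (2 over the list alone, median 0.57, adjusted p = 0.0266, and adjusted p = 0.362 with an estimated correlation). Without aged mutant 1 this call was lost (adjusted p = 0.559), as it was without aged control 2 (adjusted p = 0.459). Of the 35 genes called in B cells, 22 were ones that free RNA can bring. The rise of the effector list there can thus come from RNA of other cells. The B cell activation and plasma cell list was higher in 1 of 8 classes, B cells. There 0 of 10 members passed and 3 did over the list alone (median 0.18, adjusted p = 0.0201, and adjusted p = 0.375 with an estimated correlation). The B cell call was lost without aged control 1 (adjusted p = 0.569) without aged mutant 2 (adjusted p = 0.372) and without members that free RNA can bring (adjusted p = 0.0555).

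Endothelial cells of aged mutants expressed more vessel activation genes, while cluster 6 held 1026 of 2639 of these cells in aged controls and 1140 of 1958 in aged mutants. Of the 12 measured members of the vascular activation list 6 rose (7 adjusted over the list alone, median 1.03, camera adjusted p = 6.22e-06, and adjusted p = 0.279 with an estimated correlation). Selp, the P-selectin that slows leukocytes, rose from 1.12 ± 0.182 to 65.0 ± 62.7 CPM (log2 change 5.89 ± 0.78, n = 2 per group, edgeR adjusted p = 0.000807). The angiogenic peptide gene Apln rose by 3.22 ± 0.39, its receptor Aplnr by 2.64 ± 0.31 and Angpt2, an antagonist of vessel-stabilising Tie2 signalling, by 2.39 ± 0.28. The basement membrane collagens Col4a1 and Col4a2 rose by 1.43 ± 0.19 and 1.86 ± 0.17. The list was higher in 2 of 2 classes tested. Fibroblasts, marked by Col1a1 and related collagens, made up 102 of 4173 CD45-negative cells outside the proximal tubule in aged mutants (2.44%) and 0 of 4565 in aged controls, which allows up to 0.0657%. Their share was therefore at least 37.2-fold higher. Podocytes, the filtration cells of the glomerulus, fell from 2.12% ± 0.658 to 0.160% ± 0.0406 of the same cells (SD, n = 2, log2 change -3.61 ± 0.62, edgeR adjusted p = 1.2e-05). The fibroblast and podocyte calls were kept without each library. Intercalated cells fell from 2.57% ± 0.808 to 1.19% ± 0.0816 (adjusted p = 0.0488). The intercalated cell call was lost without aged mutant 1 (adjusted p = 0.0943), aged mutant 2 (0.191) or aged control 2 (0.284).

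Among sorted CD45+ cells, 6 of 14 immune types changed their share of immune cells in aged mutants. Gamma delta and type 17 T cells rose from 1.22% ± 0.148 to 5.46% ± 1.94 (SD, n = 2, log2 change 2.15 ± 0.43, edgeR adjusted p = 0.00379). Regulatory T cells rose from 3.05% ± 0.00929 to 8.63% ± 2.14 (1.499 ± 0.41, adjusted p = 0.0200) and neutrophils from 2.64% ± 0.526 to 8.05% ± 4.31 (1.60 ± 0.49, adjusted p = 0.0221). T cells without a subset, made of a cluster led by the naive T cell genes Dapl1, Lef1, Tcf7 and Ccr7 and another led by Klrk1 and Cxcr6, fell from 5.86% ± 0.639 to 1.84% ± 0.5001 (-1.66 ± 0.33, adjusted p = 0.00379). NK cells fell from 3.05% ± 0.360 to 0.957% ± 0.359 (-1.66 ± 0.49, adjusted p = 0.0221) and B cells from 17.9% ± 2.47 to 8.99% ± 2.05 (-0.99 ± 0.31, adjusted p = 0.0221). Macrophages averaged 30.9% and 24.04% and did not pass. All 6 calls were lost without aged control 2 (adjusted p from 0.0727 to 0.155). Without aged control 1 those of B cells, NK cells, neutrophils and regulatory T cells were lost (0.0911). Also lost were B and NK cells (0.127) and neutrophils (0.185) without aged mutant 2, and regulatory T cells without aged mutant 1 (0.0785). The number of changed types was 0, 2 and 3 without aged control 2, aged control 1 and aged mutant 2. In the separate clustering of immune cells, most neutrophils of aged controls sat in cluster 11, led by Retnlg and S100a9 (2.44% of immune cells). Cluster 17 of the same clustering, led by Cxcl2 and Il1rn, held 5.62% ± 4.10 in aged mutants, where cluster 11 held 2.43% ± 0.204. Cluster 17 held 83 of 3057 immune cells in aged mutant 1 and 218 of 2560 in aged mutant 2.

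**Figure D2:**
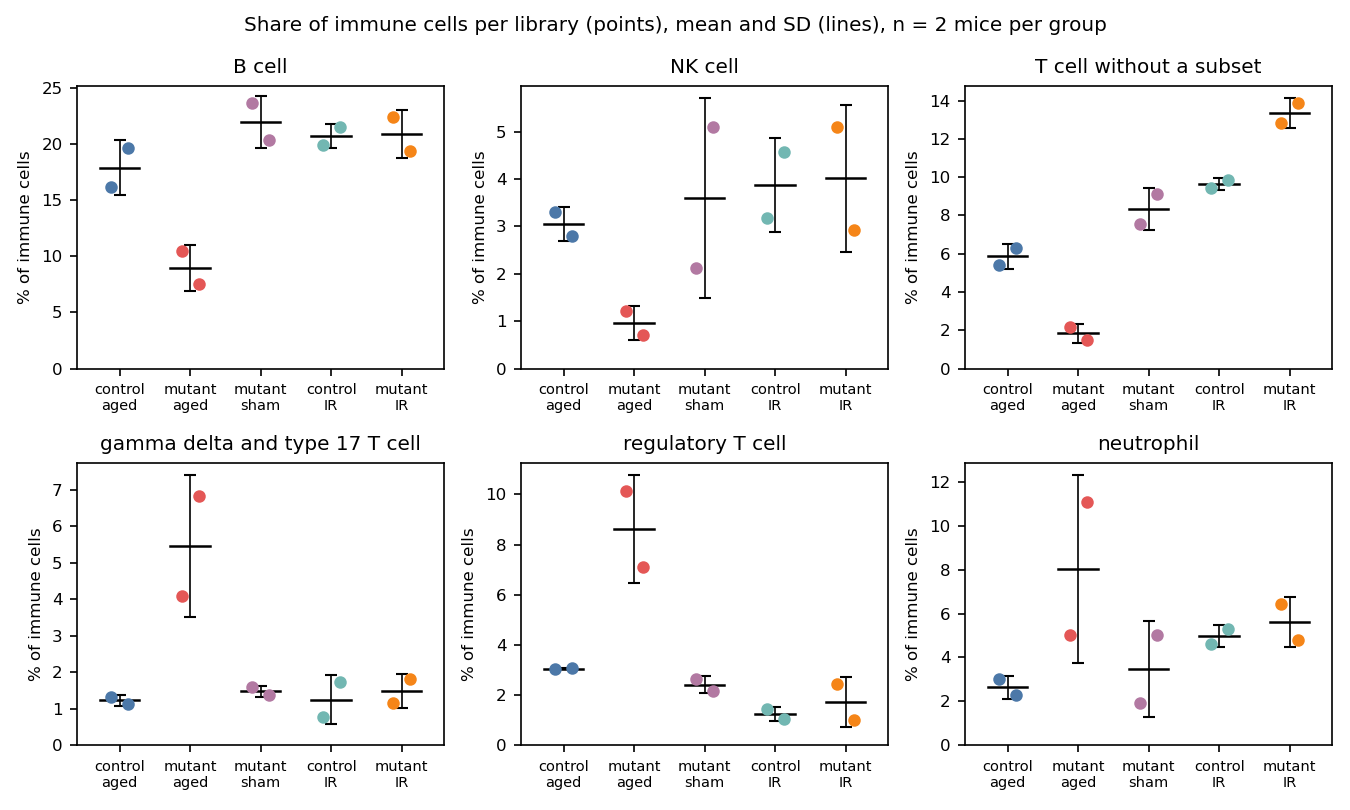
Percent of immune cells in each library for 6 immune types in the 5 groups, with a point per library and the mean ± SD of each group. Regulatory T cells averaged 8.63% in aged mutants and 1.25% to 3.05% in the other groups, and T cells without a subset averaged 1.84% in aged mutants and 5.86% to 13.3% elsewhere.

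Over all 13 tested classes, 7874 gene and class pairs passed the edgeR test in aged mutants against aged controls, 4212 higher and 3662 lower. Principal cells gave 3150 (1523 higher, 1627 lower), thick ascending limb cells 1340, dendritic cells 887, endothelial cells 728, macrophages 652 and proximal tubule cells 403, and pericytes 0 (531 at an unadjusted p under 0.05). In this contrast, 29 of the 30 genes named by size kept their call without each library. The total was 4247 without aged control 2, 4444 without aged control 1, 3561 without aged mutant 2 and 4313 with DESeq2. Principal cells of controls came mostly from clusters 16 and 20 and those of aged mutants from clusters 25 and 29. Within cluster 25 alone, a choice made after seeing the data, 104 genes passed. That cluster held 152 of 771 principal cells in aged controls and 579 of 1241 in aged mutants, so fewer cells can lower the count. Clusters were drawn from the same counts, so this number does not show how much comes from the mix. Camera called 104 list and class pairs of 247 tested (79 higher, 25 lower). The count was 41 of 135 tested without members that free RNA can bring (20 higher, 21 lower). Lists left with under 5 members dropped out, and among the pairs still tested there was no excess of higher ones. With an estimated correlation the count over all members was 0 (47 at an unadjusted p under 0.05).

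The comparison of injured mutants with injured controls asks what the mutation does 8 weeks after injury. The median mitochondrial share of kept cells was 12.6% and 11.4% in injured mutants, 9.26% and 6.94% in injured controls and 10.1% and 10.9% in sham mutants, so cell quality or the mix of cells went with genotype here. With a mitochondrial limit of 25%, 180 gene and class pairs passed in place of 294. Proximal tubule cells of injured mutants had more Serpina1d, a secreted antiprotease (chromosome 12, 103763594 to 103773592), which rose from 2.08 ± 0.449 to 27.6 ± 5.18 CPM (log2 change 3.70 ± 0.27, n = 2 per group, edgeR adjusted p = 9.74e-06). The sugar transporter Slc5a10 rose from 41.8 ± 6.47 to 290 ± 16.2 CPM (2.79 ± 0.32, adjusted p = 0.000789). Cdkn1a, the cell cycle inhibitor p21, rose there from 8.54 ± 6.20 to 51.7 ± 1.98 CPM (2.64 ± 0.34, adjusted p = 0.00277) and the carboxylesterase Ces1f by 1.75 ± 0.18. Spns3, a member of a lipid transporter family (chromosome 11, 72494919 to 72550506), fell from 68.7 ± 4.22 to 8.76 ± 2.32 CPM (-2.98 ± 0.18, adjusted p = 1.59e-06). The kinase Nuak2 fell by 1.93 and the basement membrane protein gene Lad1 by 2.04. In thick ascending limb cells Esr1, the estrogen receptor alpha (chromosome 10, 4611593 to 5005614), rose from 0.841 ± 0.157 to 25.1 ± 6.63 CPM (4.82 ± 0.45, adjusted p = 9.77e-06). Fosb, an immediate early factor, fell by 3.39 and Klhdc8a by 1.92. Fosb was high in injured controls, at 29.4 ± 9.59 CPM against 6.64 ± 4.52 CPM in aged controls. In principal cells Ntn4, a netrin of basement membranes (chromosome 10, 93640681 to 93747207), fell from 246 ± 2.86 to 64.4 ± 12.2 CPM (-1.94 ± 0.16, adjusted p = 6.07e-05). Spns2, a sphingosine-1-phosphate exporter, fell by 1.63 and Lad1 by 1.48. These 13 calls were the ones, of 30 genes named by size, that were kept without each library.

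Other calls in this contrast were lost when 1 library was left out. In principal cells Grem1, a secreted antagonist of bone morphogenetic proteins (chromosome 2, 113746164 to 113758646), rose from 10.4 ± 5.91 to 109 ± 66.8 CPM (log2 change 3.39 ± 0.52, n = 2 per group, edgeR adjusted p = 0.00537). The Grem1 call was lost without injured control 2 (log2 change 2.90, adjusted p = 0.132) and without injured mutant 2 (2.56, adjusted p = 0.117). Dcdc2a rose from 3.53 ± 1.203 to 21.5 ± 7.73 CPM (2.57 ± 0.40, adjusted p = 0.00540), lost without injured mutant 1 (2.16, adjusted p = 0.130) and without injured control 2 (2.25, adjusted p = 0.106). In thick ascending limb cells Nos1 fell by 2.21, lost without injured control 1 (-2.07, adjusted p = 0.0787), without injured mutant 2 (-2.04, adjusted p = 0.0928) and with DESeq2 (-2.21).

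Lists of proximal tubule transcripts were higher in other classes of injured mutants. A check list of 13 abundant proximal tubule transcripts such as Kap, Gpx3 and Miox, and the proximal tubule transport and metabolism list, were each higher in 13 of 14 classes. Proximal tubule cells themselves were the exception, with medians of 0.22 and 0.16 (camera adjusted p = 0.178 and 0.315). In 9 of the 13 other classes 0 members of the check list passed by themselves in the edgeR test, and in intercalated cells its summed level was 8594 CPM in injured mutants and 8817 CPM in injured controls. The check list's median log2 change was 1.66 in principal cells, with 8 of 13 members higher (12 adjusted over the list alone, adjusted p = 1.05e-09, and adjusted p = 0.514 with an estimated correlation). It was 1.46 in B cells, with 7 of 13 higher (12 over the list alone, adjusted p = 2.45e-12, and adjusted p = 0.514 with an estimated correlation). The transport list rose in principal cells with 9 of 18 members higher (16 over the list alone, median 1.76, adjusted p = 2.84e-14, and adjusted p = 0.514 with an estimated correlation). In B and T cells, which should lack these genes, the check list summed to 2072 and 2281 CPM in the injured mutants, 1007 and 1101 CPM in the injured controls. It summed to 1066 and 2049 CPM in the sham mutants, 1426 and 793 CPM in the aged mutants and 816 and 990 CPM in the aged controls. Of the genes called in this contrast, 35.0% had a mean under 0.1 of that in their highest class, including all 16 called in B cells, so such genes were not named.

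**Figure D3:**
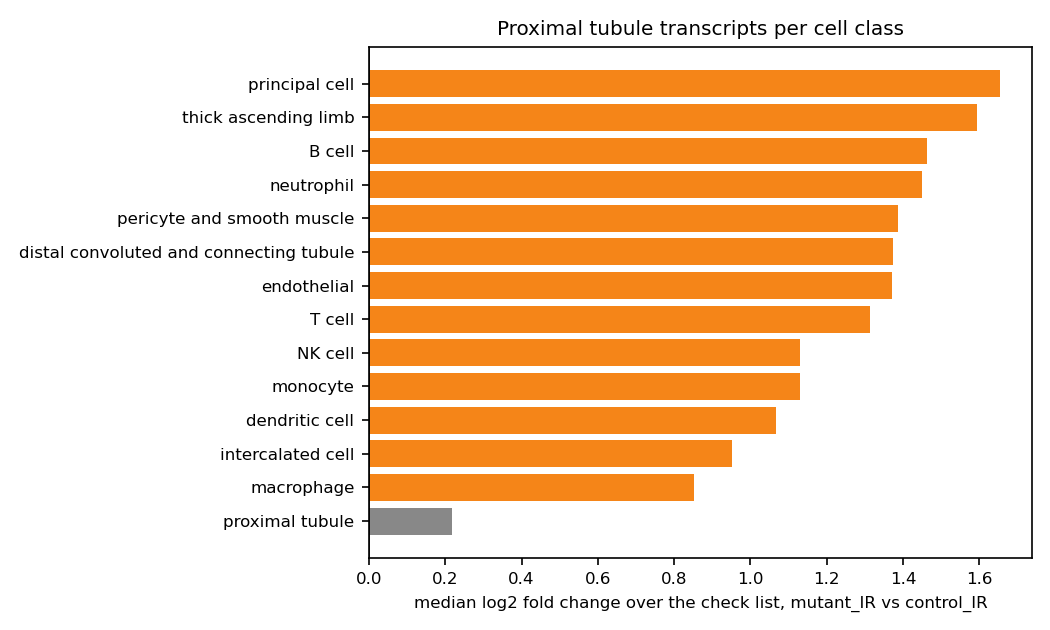
Median log2 fold change of 13 abundant proximal tubule transcripts in injured mutants against injured controls, a bar per cell class, with proximal tubule cells in grey. The median was 0.22 in proximal tubule cells and 0.85 to 1.66 in the other 13 classes.

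Among the other lists, cell cycle genes were higher in 3 and lower in 1 of 11 classes in injured mutants. In NK cells 1 of 8 members rose (6 adjusted over the list alone, median 2.24, camera adjusted p = 1.15e-09, and adjusted p = 0.514 with an estimated correlation). Proximal tubule cells had 1 of 20 higher (7 over the list alone, median 1.16, adjusted p = 3.09e-08, and adjusted p = 0.514 with an estimated correlation). MHC class II genes were lower in 1 of 10 classes, monocytes, with 0 of 8 past the test and 6 over the list alone (median -0.86, adjusted p = 1.09e-07, and adjusted p = 0.514 with an estimated correlation). A monocyte cluster of the immune cell clustering held 122 cells in injured mutant 2 and 0 to 13 in every other library. The fall in monocytes can thus come from the mix. Immediate early and stress genes were lower in 6 of 14 classes, where the injured controls had themselves more of them than aged controls in 9 of 15 classes. In dendritic cells 1 of 22 fell (5 over the list alone, median -0.38, adjusted p = 4.99e-08, and adjusted p = 0.514 with an estimated correlation). The alternative activation list was higher in macrophages with 0 of 12 members past the test and 5 over the list alone (median 0.99, adjusted p = 0.000700, and adjusted p = 0.514 with an estimated correlation). This was lost without injured mutant 2 (adjusted p = 0.170). The tubular injury list was higher in proximal tubule cells with 1 of 20 members higher (1 over the list alone, median 0.35, adjusted p = 0.0334, and adjusted p = 0.754 with an estimated correlation). The injury list call was lost without injured control 1 (adjusted p = 0.329), injured mutant 2 (0.129) or sham mutant 1 (0.0927). The interferon list was higher in dendritic cells with 1 of 20 members higher (2 over the list alone, median 0.20, adjusted p = 0.0181, and adjusted p = 0.720 with an estimated correlation). The interferon call was lost without injured mutant 1 (adjusted p = 0.905) without injured control 2 (adjusted p = 0.248) and without members that free RNA can bring (adjusted p = 0.0577). The naive lymphocyte, vascular activation, T and NK effector, B cell activation, TGF-beta, YAP and TEAD, glycolysis and cilium lists passed in 0 classes.

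No immune type passed the edgeR test between injured mutants and injured controls (0 of 14, with 2 at an unadjusted p under 0.05, 0 by limma on logit shares). Macrophages averaged 13.9% ± 0.606 and 29.3% ± 0.540 of immune cells (SD, n = 2, log2 difference -1.08 ± 0.33, adjusted p = 0.0913) and monocytes 14.5% ± 1.83 and 7.48% ± 0.106 (0.95 ± 0.32, adjusted p = 0.0913). The number of changed types was 1 without sham mutant 1. Among CD45-negative cells outside the proximal tubule, distal convoluted and connecting tubule cells rose from 4.71% ± 2.07 to 14.3% ± 3.05 (1.59 ± 0.44, adjusted p = 0.00820) and podocytes fell from 4.03% ± 0.971 to 1.51% ± 0.128 (-1.40 ± 0.46, adjusted p = 0.0209). Each of these calls was lost without injured mutant 1 (adjusted p = 0.0794), injured control 2 (0.2005) or injured mutant 2 (0.0799). In all, 294 gene and class pairs passed over 14 classes, 221 higher and 73 lower. Principal cells gave 143, thick ascending limb cells 70 and proximal tubule cells 40. The total was 182 without injured control 1 (46.7% higher), 104 without injured mutant 1, 86 without injured control 2 (44.2% higher) and 80 without injured mutant 2. It was 938 with only the compared groups in the fit, 1715 without the low-count filter, 167 without genes that free RNA can bring and 151 with 1 adjustment over all classes. Camera called 55 of 255 list and class pairs (45 higher, 10 lower). Leaving out members that free RNA can bring gave 9 of the 143 pairs still tested (4 higher, 5 lower). Among these pairs there was no excess of higher ones. An estimated correlation gave 0 (18 at an unadjusted p under 0.05).

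Some genes went the same way in both cohorts, which share no library. Both contrasts came from the same fit, with the spread of each gene estimated over all 10 libraries. The calls are thus not independent, and the products given below are no exact measure of what unrelated effects would give. Among 10006 genes tested in principal cells in both, counting genes at 0.1 or more of their highest class, 36 were higher in mutants in both the aged and the injury cohort, of 1098 and 72 called, where the product of the calls over the genes is 7.90. Lower in both were 20, of 1523 and 29 called, against 4.41. In proximal tubule cells 8 were higher and 5 lower in both, against 0.335 and 0.1002. Ntn4 in principal cells averaged 214 ± 18.3 CPM in aged controls and 52.0 ± 1.48 CPM in aged mutants, and 30.3 ± 12.1 CPM in sham mutants.

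The comparison of injured with sham mutants asks what injury adds in cilia mutants. In T cells the glutaredoxin gene Glrx, which reverses oxidation of protein thiols (chromosome 13, 75839868 to 75850154), fell from 133 ± 24.9 to 70.0 ± 6.45 CPM (log2 change -0.99 ± 0.14, n = 2 per group, edgeR adjusted p = 0.0351). It was the 1 gene past the test in 11 classes, with 5003 gene and class pairs at an unadjusted p under 0.05 and 15 by DESeq2. The Glrx call was lost without sham mutant 2 (adjusted p = 0.141), without injured mutant 2 (adjusted p = 0.181) and with only the compared groups in the fit (adjusted p = 0.0923). The naive lymphocyte list was higher in T cells of injured mutants with 0 of 10 members past the test over all genes and 9 over the list alone (median 0.76, camera adjusted p = 2.41e-07, and adjusted p = 0.949 with an estimated correlation). MHC class II genes were lower in T cells with 0 of 7 members past the test and 1 over the list alone (median -0.56, adjusted p = 0.00955, and adjusted p = 0.949 with an estimated correlation), lost without sham mutant 2 (adjusted p = 0.336) and injured mutant 1 (adjusted p = 0.825). The MHC class II fall in T cells can come from RNA of other cells. The proximal tubule transport list was higher in 10 of 11 classes. In principal cells 0 of 18 members passed and 2 did over the list alone (median 0.85, adjusted p = 1.91e-08, and adjusted p = 0.949 with an estimated correlation). No immune type passed the edgeR test (0 of 14, with 0 at an unadjusted p under 0.05 and 0 by limma). T cells without a subset averaged 13.3% ± 0.772 in injured and 8.33% ± 1.08 in sham mutants (log2 difference 0.67 ± 0.32, adjusted p = 0.423), and no CD45-negative type passed. The number of genes was 5, 59, 19 and 21 without sham mutant 1, sham mutant 2, injured mutant 1 and injured mutant 2, and 658 without the low-count filter. Camera called 32 of 218 pairs, and 0 with an estimated correlation (5 at an unadjusted p under 0.05). Without members that free RNA can bring it called 4 of the 120 pairs still tested.

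Injured and aged mutants are the groups whose pace of cyst growth the study set side by side, and here cohort, time since induction and injury cannot be told apart. Principal cells of injured mutants had more Klk1 than those of aged mutants, 14520 ± 3412 against 347 ± 316 CPM (log2 change 5.41 ± 0.49, n = 2 per group, edgeR adjusted p = 3.31e-06). Sgk1, a kinase that raises sodium reabsorption, was also higher there, 351 ± 103 against 9.29 ± 5.07 CPM (5.10 ± 0.55, adjusted p = 1.13e-05). Sgk1 also averaged more in injured than in aged controls, 357 ± 7.47 against 60.4 ± 44.7 CPM. Il1f6 was at least 85.5-fold lower and Gxylt2 at least 25.2-fold lower against the floor of 3 counts, and the Il1f6 call was not kept by DESeq2 (adjusted p = 0.194). Ankrd1 was lower in injured mutants with a ratio of 221 (95% counting interval 39.4 to 8723). In principal cells of injured mutants 15 of 19 tubular injury genes were lower and 1 higher (16 and 1 adjusted over the list alone, median -1.98, camera adjusted p = 2.40e-09, and adjusted p = 0.197 with an estimated correlation). In the same cells 17 of 17 oxidative phosphorylation genes were higher (17 over the list alone, median 0.77, adjusted p = 1.72e-10, and adjusted p = 0.330 with an estimated correlation). In T cells 8 of 10 naive lymphocyte genes were higher (8 over the list alone, median 1.61, adjusted p = 8.31e-11, and adjusted p = 0.277 with an estimated correlation). T cells without a subset were a larger share of immune cells in injured mutants (13.3% ± 0.772 against 1.84% ± 0.5001, 2.85 ± 0.34, edgeR adjusted p = 9e-05), as were NK cells (2.03 ± 0.50, adjusted p = 0.00747) and B cells (1.21 ± 0.31, adjusted p = 0.00830). Regulatory T cells (-2.41 ± 0.44, adjusted p = 0.00187) and gamma delta and type 17 T cells (-1.83 ± 0.44, adjusted p = 0.00747) were smaller. The NK, B and gamma delta calls were lost without aged mutant 2 (adjusted p = 0.0698), which left 2 changed types of 5. Outside the leukocytes, distal convoluted and connecting tubule cells (2.23 ± 0.45), podocytes (3.13 ± 0.67) and thick ascending limb cells (1.04 ± 0.36) were larger shares and endothelial cells (-0.92 ± 0.37) a smaller one. Fibroblasts were 0 of 2821 cells, which allows up to 0.106%, at least 22.98-fold lower. The endothelial call was lost without aged mutant 1 (adjusted p = 0.0755), aged mutant 2 (0.10001) or injured mutant 2 (0.106), and the thick ascending limb call without aged mutant 2 (0.0696). Over all 6 contrasts 12 changes of CD45-negative types passed, and 7 without aged mutant 2. In all, 8637 gene and class pairs passed over 12 classes (4211 higher, 4426 lower), 3701 without aged mutant 2, 4184 without injured mutant 1, 4085 without injured mutant 2 and 4511 with DESeq2. Camera called 110 of 230 pairs (44 higher, 66 lower). Leaving out members that free RNA can bring gave 40 of the 127 pairs still tested (22 higher, 18 lower). Among these pairs there was no excess of lower ones. An estimated correlation gave 0 (34 at an unadjusted p under 0.05).

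The controls of the 2 cohorts differed far less, though this comparison has the same confounding. In T cells of injured controls Ccr7, the homing receptor of naive T cells (chromosome 11, 99144196 to 99155077), averaged 189 ± 31.7 CPM against 66.9 ± 0.402 CPM in aged controls (log2 change 1.52 ± 0.18, n = 2 per group, edgeR adjusted p = 0.00296). Tsc22d3, a glucocorticoid-induced regulator, rose by 1.65 ± 0.28 (adjusted p = 0.0289). Both calls were lost without aged control 1 (adjusted p = 0.0806 and 0.261), without aged control 2 (0.0835 and 0.112) and without injured control 2 (0.111 and 0.431). Of the 6 named genes 0 kept their call without each library. Naive lymphocyte genes were higher in T cells, 6 of 10 (10 adjusted over the list alone, median 0.82, camera adjusted p = 1.57e-08, and adjusted p = 0.930 with an estimated correlation). In dendritic cells 4 of 20 interferon genes were lower (1 higher and 11 lower over the list alone, median -0.77, adjusted p = 3.11e-08, and adjusted p = 0.930 with an estimated correlation). Immediate early and stress genes were higher in 9 of 15 classes, among them dendritic cells with 3 of 22 (10 over the list alone, median 0.40, adjusted p = 5.61e-07, and adjusted p = 0.870 with an estimated correlation). In all, 155 gene and class pairs passed over 15 classes (77 higher, 78 lower), 11 of them in principal cells. The count was 35 without injured control 2, 262 without sham mutant 1, 744 with only the compared groups in the fit and 2159 without the low-count filter. No immune or CD45-negative type passed the edgeR test (0 of 14 immune types, with 2 at an unadjusted p under 0.05 and 0 by limma). Camera called 33 of 266 pairs (17 higher, 16 lower), and 0 with an estimated correlation (9 at an unadjusted p under 0.05).

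Whether the effect of the mutation differed between the cohorts was tested as an interaction, in which a cohort shift shared by both genotypes cancels. In principal cells the effect on Klk1 was higher in the injury than in the aged cohort by 5.82 ± 0.62 on the log2 scale (n = 2 per group, edgeR adjusted p = 9.29e-05), since Klk1 averaged 14520 ± 3412 CPM in injured mutants and 10292 ± 1058 CPM in injured controls. Its paralogs Klk1b9 and Klk1b5 differed by 4.13 ± 0.66 and 4.11 ± 0.41, with reads uncertain between the family. The effect on Pigr was lower by -5.82 ± 0.82 (adjusted p = 0.000749). Gxylt2 averaged 20.2 ± 5.94 CPM in aged mutants and 0 UMIs in injured mutants (adjusted p = 0.00556), lost without injured control 1 (adjusted p = 0.128). The Ankrd1 difference of -6.23 ± 1.67 (adjusted p = 0.0280) was lost without aged control 2 (0.0549), injured control 1 (0.129), injured control 2 (0.131) or injured mutant 2 (0.0939). The tubular injury list differed in 10 of 12 classes. In principal cells 10 of 19 members had a lower effect in the injury cohort (1 higher and 12 lower adjusted over the list alone, median -1.77, camera adjusted p = 4.20e-09, and adjusted p = 0.224 with an estimated correlation). The effect was higher for 14 of 17 oxidative phosphorylation genes (17 over the list alone, median 0.58, adjusted p = 1.27e-08, and adjusted p = 0.353 with an estimated correlation). The naive lymphocyte list differed in T cells, with 2 of 10 higher (6 higher and 1 lower over the list alone, median 0.90, adjusted p = 0.000810, and adjusted p = 0.443 with an estimated correlation), lost without injured mutant 2 (adjusted p = 0.0990). In all, 1859 gene and class pairs passed over 12 classes (1015 higher, 844 lower), with 1086 in principal cells and 538 in thick ascending limb cells. The total was 2997 without aged mutant 1, 1156 without aged control 1, 986 without aged control 2, 962 without aged mutant 2, 959 without injured mutant 1, 990 without injured mutant 2, 1102 without injured control 2 and 4234 without the low-count filter. In principal cells 340 genes passed without cluster 29 and 5 in cluster 25 alone, both chosen after seeing the data. Cluster 25 held 66 of 752 principal cells in injured controls and 115 of 660 in injured mutants. It held 152 of 771 in aged controls and 579 of 1241 in aged mutants. Fewer cells can thus lower these numbers, which do not show how much comes from the mix. T cells without a subset were the 1 immune type whose genotype effect differed (2.13 ± 0.45, edgeR adjusted p = 0.0108), lost without aged mutant 2 (0.0511), aged control 2 (0.0736) or injured control 2 (0.0506). The number of such types was 2 without injured control 1 or injured mutant 1 and 3 without injured mutant 2. Distal convoluted and connecting tubule cells differed by 2.31 ± 0.62 (adjusted p = 0.00714), lost without aged mutant 2 (0.235) and injured mutant 1 (0.0670). Podocytes differed by 2.21 ± 0.81 (adjusted p = 0.0426), lost without either aged mutant (0.192 and 0.235), either injured mutant (0.0670 and 0.0798), aged control 1 (0.158) or injured control 1 (0.136). Camera called 97 of 230 pairs (42 higher, 55 lower), with the proximal tubule check list and transport list among the higher in 11 and 12 of 12 classes. Leaving out members that free RNA can bring gave 34 of the 127 pairs still tested (18 higher, 16 lower). Among these pairs there was no excess of lower ones. An estimated correlation gave 0 (32 at an unadjusted p under 0.05).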

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

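All tests of explanations in this part were chosen after the results were seen. The results below stand out because the effect of the mutation differed between the injury and the aged cohort in a test of that difference, or because a signal appeared in cells that entered no comparison.

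In all classes, 1859 gene and class pairs and 97 list and class pairs differed in genotype effect between the cohorts. Without members that free RNA can bring 34 of the 127 list and class pairs still tested passed (18 higher, 16 lower). Over all members the 2 lists of proximal tubule transcripts were among the higher in 11 and 12 of 12 classes. With an estimated correlation 0 of the list and class pairs passed in camera (32 at an unadjusted p under 0.05). In principal cells the difference was 5.82 for Klk1, 4.13 for Klk1b9 and 4.11 for Klk1b5, higher in the injury cohort, and -10.11 for Gxylt2, -6.23 for Ankrd1 and -5.82 for Pigr on the log2 scale. The fitted Gxylt2 value has a group at 0 UMIs and is no bound. The technical readings below were set against this pattern. Without aged mutant 2, 99.9% of the principal cell calls kept their sign and at least 0.5 of their size. Aged mutant 1 thus showed these effects too. The calls were chosen with both aged mutants in the fit, which favours genes on which they agree. How far aged mutant 2 adds to the number of calls is therefore not decided. Unequal total UMIs of principal cells do not carry the pattern alone, since 793 genes were called after thinning to equal totals, against 1086 before. Cell numbers and UMIs per cell were not matched, so their part stays open. A shift between the cohorts that acts alike on both genotypes on the log2 scale cancels in this difference by construction. The pattern may reflect time since induction, age, injury or cyst stage, which the design does not separate. The clusters that hold principal cells also differ between the groups. The 5 calls in cluster 25 alone do not decide the part of this mix. That cluster held 66 of 752 principal cells in injured controls and 115 of 660 in injured mutants, and clusters were drawn from the same counts.

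T cells without a subset had a genotype effect higher by 2.13 in the injury cohort, since their share was low in aged mutants. Less blood left in aged mutant kidneys may explain this, since B and NK cells fell with them. Red cell transcripts do not help to decide, as red cells were lysed and the values did not follow the share. They were 2.82 and 11.4 CPM in aged mutants against 59.2 and 35.8 in aged controls, but also 3.11 CPM in injured mutant 1, where the share was 12.8%, and 1.05 CPM in sham mutant 1, where it was 7.57%. The share of the circulating-like neutrophil cluster 11 of the immune cell clustering, which less blood would lower, had a log2 ratio of -0.00614. Neutrophils entering the tissue could hide a loss, so blood and tissue origin cannot be told apart. Cells moving between T cell subset names also stay open. The naive lymphocyte list over all T cells had a median log2 change of -0.78 (camera adjusted p = 1.93e-05, and adjusted p = 0.306 with an estimated correlation), but all T cells together went from 25.9% to 39.3% of immune cells, and growth of other subsets thins naive transcripts in either case. A change in the T cells of the tissue stays open and was not tested.

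The share of distal convoluted and connecting tubule cells differed in genotype effect by 2.31, and that of podocytes by 2.21. An unnamed cluster led by Cryab, Ptgds, C3, Spp1 and Cp held 2.18% and 6.08% of singlets in the aged mutants and 0.235% to 0.740% in every other library.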

How the results depend on the processing

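Counts of the aged and injured libraries thinned to equal totals per class, the fits without sham mutant 1 and those on subsets of principal cell clusters were chosen after seeing the data. Where no reason is given below, the cause was not tested. Of the counts that answer a comparison, 180 alternative values stayed within 1.5 times and 65 did not. Of the other results, 3639 kept their direction and side of the threshold, 551 kept only the direction, 17 moved and 3 reversed.

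For aged mutants against aged controls, 7874 genes became 4313 with DESeq2 and 5161 when thinned. For injured mutants against injured controls, 294 became 1715 without the low-count filter, 938 with only the compared groups, 180 at a mitochondrial limit of 25%, 167 without genes that free RNA can bring and 151 with 1 adjustment over all classes. For injured against sham mutants, 1 became 15 with DESeq2, 658 without the filter, 5 with only the compared groups, 2 with doublets kept, 5 at resolution 0.5, 0 with 1 adjustment over all classes and 6 when thinned. For injured against aged mutants, 8637 became 4511 with DESeq2. For injured against aged controls, 155 became 2159 without the filter and 744 with only the compared groups. For the difference between cohorts, 1859 became 4234 without the filter and 940 at resolution 0.5.

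Leaving out 1 library gave, for these contrasts in the same order, 3561 to 8870, 80 to 348, 5 to 59, 3701 to 9592, 35 to 262 and 959 to 2997 genes. It gave 0 to 6, 0 to 1, 0 to 0, 2 to 7, 0 to 0 and 0 to 3 immune types, and 7 to 12 CD45-negative types. It gave 100 to 125, 39 to 76, 23 to 39, 106 to 121, 22 to 38 and 82 to 109 list and class pairs.

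With an estimated correlation 0 list and class pairs passed in each of the 6 contrasts. Without members that free RNA can bring, fewer members and fewer pairs were tested. The aged comparison then gave 41 of 135 pairs, injured mutants against injured controls 9 of 143 and injured against sham mutants 4 of 120. Injured against aged mutants gave 40 of 127 and the difference between cohorts 34 of 127.

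Directions reversed in 3 cases, all in principal cells of aged mutants against aged controls: Isg15 was -0.10 and Ift88 0.27 at resolution 0.5, and Cxcl10 was 0.47 with doublets kept. In principal cells, the aged comparison gave 104 genes in cluster 25 alone. Injured mutants against injured controls gave 57 without cluster 29 and 5 in cluster 25, and the difference between cohorts 340 and 5. These subsets hold fewer cells, which can lower the counts.

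Replicate numbers gave no sign of pairing: over 15 classes the correlation of paired differences had a median of -0.02. A replicate block gave 7368 genes in the aged comparison and 1885 for the difference between cohorts, and a crossed block 8379 and 2200. Total UMIs per class limit how many genes are called: when thinned, 294 became 216 for injured mutants against injured controls, 8637 became 5873 for injured against aged mutants, 155 became 127 for the controls and 1859 became 1367 for the difference between cohorts. Injured against sham mutants went from 1 to 6, where the sham libraries were not thinned. Which sizes of change depth limits was not tested.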

Other observations

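All tests of explanations in this part were chosen after the results were seen. Sham mutants and injured controls, which differ in both genotype and injury, were not compared in any contrast. For 5 calls of the injury cohort, picked after their values were seen, sham mutants lay on the same side of injured controls as injured mutants did. Esr1 in thick ascending limb cells averaged 22.0 ± 4.76 CPM in sham mutants, 25.1 ± 6.63 CPM in injured mutants and 0.841 ± 0.157 CPM in injured controls (SD, n = 2). In proximal tubule cells Serpina1d averaged 29.9 ± 5.87, 27.6 ± 5.18 and 2.08 ± 0.449 CPM, Slc5a10 312 ± 8.47, 290 ± 16.2 and 41.8 ± 6.47 CPM, and Spns3 6.97 ± 0.993, 8.76 ± 2.32 and 68.7 ± 4.22 CPM in the same order. Lad1 in principal cells averaged 18.4 ± 1.65, 35.9 ± 3.84 and 101 ± 19.2 CPM, with injured mutants above sham mutants.

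Proximal tubule transcripts were higher in injured mutants than in injured controls in other classes. RNA freed from proximal tubule cells may be the source, but the test does not decide. The rank correlation of the rise in CPM with the level in proximal tubule cells was above 0.5 in 13 of 13 other classes, but the levels in injured controls followed proximal tubule cells already (0.511 to 0.989), so any proportional rise gives this. In intercalated cells the list summed to 8594 CPM in injured mutants and 8817 CPM in injured controls. For droplets holding a proximal tubule cell beside a B or T cell the test does not decide either. The 5% of B and T cells with most of these UMIs held 12.6% of them in injured mutants and 17.2% in injured controls. The rise thus did not sit in a few of the counted cells. Likely doublets had been left out before, so such droplets may have been removed from the count. Whether handling of the tissue or damage in the animal plays a part was not tested.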
